A study of Mus musculus with 4 samples.

How the data were processed

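Messenger RNA levels were measured on single-colour Affymetrix mouse whole-genome expression arrays in dorsal skin at postnatal day 16. Per the labels, 2 arrays held skin of wild type mice and 2 held skin of bitransgenic mice that overexpressed deltaNp63alpha, the p63 isoform that lacks the amino-terminal transactivation domain and carries the alpha tail. Each array held RNA of a different animal, as the labels call the arrays of a group biological replicates. Per the labels' protocols, total RNA was purified with TRIzol and a spin column, and was turned into biotinylated cRNA by the array maker's standard procedure. The labels give no litter, sex, hybridisation date or inducing treatment.

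The values are probe set signals, in units of array intensity on a linear scale, as deposited by the authors. MAS5, which summarises perfect-match and mismatch probes into 1 signal per probe set, and the affy package are named per the submitters' processing notes. Their versions, and which step each was used for, are not given in the sources used here. In the deposited values the mean of each array, with 2% of the probe sets trimmed at each end, lay between 499.5 and 500.0, so the arrays had been scaled to a common mean. Such scaling makes each value relative to the rest of its array, so a change in total RNA per cell would not be seen. The value table holds signals without detection calls, so low signals were handled by a filter and not by a call of presence.

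The table held 45101 probe sets, of which 64 were controls. Gene names came from the platform annotation, in which 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Of the probe sets with 1 symbol, 34741 matched a RefSeq gene by Entrez identifier in a table for assembly GRCm38.p6, which changed 0 symbols. No genome build of the probe sets is given in the sources used here, so no coordinates are printed. Probe sets with several symbols were named for no gene.

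Signals were transformed as log2(signal + 16), with no further normalization between arrays. A probe set was kept when its mean over all 4 arrays was at or above the 40th percentile of all probe sets that were not controls, which was 6.19 on the log2 scale or a signal of 57.0. This kept 27022 probe sets. Where several probe sets of a gene were kept, the one with the highest mean over the 4 arrays stood for the gene, which applied to 5966 of the 13070 genes tested. The pseudocount of 16 pulls folds toward 0 for genes whose signal is near or below the filter in a group, so folds of such genes depend on it.

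Groups were taken from the labels. Bitransgenic and wild type skin were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The fit had 2 residual and 4.45 prior degrees of freedom, and standard errors (SE) and 95% confidence intervals are those of the moderated fit. Every Trp63 probe set was also tested by itself in a fit of all 45037 probe sets that were not controls. On simulated data with the spread of these arrays, 200 of 13070 genes were changed in each of 20 draws. The simulated genes varied independently of each other. The test called 0.746% of genes changed by 1 on the log2 scale, 37.3% of those changed by 2 and 95.8% of those changed by 4, and 4.62% of its calls were false. A miss of the threshold therefore says little about changes of 2-fold to 4-fold.

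Before the data were examined, 34 gene lists were fixed from knowledge of skin, hair follicle and p63 biology, including markers of the other cell types that a piece of skin can hold. Of these, 33 were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with adjustment over the lists. The list of Y-linked genes and Xist only served to look at the sex of the animals. Camera was also run with the correlation estimated from these arrays, a test that has only the 2 residual degrees of freedom of the fit. With no effect simulated, 3 of 660 lists were called at the preset correlation. The simulated genes were independent, while the correlation estimated within lists on these arrays reached 0.848, for skeletal muscle. That count therefore does not show how often camera would err on these arrays. For each list, members past the threshold were counted over all genes and also adjusted over the list alone. The rule for naming picked Trp63, the 8 genes with the largest rise and the 8 with the largest fall. These rises and falls were taken among genes past the threshold with no overlap between groups. The rule also picked the 3 members with the smallest p of each list that passed camera. For any other list that held a called gene, it picked the member with the smallest p. Picked genes are called named genes below, although the text prints only part of them. Symbols of unnamed clones and predicted genes were left out. Other genes named in the text were chosen after their values were seen, apart from those that name every called member of a list and those that served to check RNA and sex.

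The signals of 24 probe sets for Bacillus RNAs, which are spiked in before labelling, split the arrays by replicate number and not by genotype. Replicate number was therefore treated as a possible labelling batch that held both groups, although the labels state no batch and a different dose of the spike would give the same split. The block takes up 1 of the 2 residual degrees of freedom, so p values with the block rest more on the prior of the fit. Arrays of the same number also differed in Xist and Y-linked signal. The adjusted p or count with it as a block is given beside a result where the block changed the call or moved the count by over 1.5 times, and medians within each number are given for lists that passed camera. The alternatives tried were quantile normalization, equal array medians, no filter, a filter at the 60th percentile, pseudocounts of 1 and 64, eBayes without the trend or with robust settings, the mean of a gene's probe sets, leaving out probe sets with suffix _x_at or _s_at, the replicate block, leaving out each array in turn, testing each probe set by itself and the estimated correlation. Control probe sets were left out of every test. Figures were drawn with matplotlib 3.10.9.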

Results

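Gene expression was profiled in dorsal skin of 2 wild type and 2 bitransgenic mice at postnatal day 16, a time at which the first growth phase of mouse hair is near its end. The bitransgenic mice overexpressed deltaNp63alpha, the main p63 isoform of basal keratinocytes and a transcription factor of stratified epithelia. Each animal gave 1 array (n = 2 per group throughout), and the number of arrays limits the precision of every value. Array signals ran from 0.1 to between 33303 and 53465 at the brightest probe set, and the median signal lay between 97.9 and 113.1. Over 27022 probe sets, the correlation between arrays was 0.918 for the wild type arrays and 0.949 for the bitransgenic arrays. Across genotypes it ran from 0.869 to 0.920, and wild type replicate 2 was as close to bitransgenic replicate 2 as to the other wild type array. The ratio of 3' to 5' signal for Gapdh, a measure of RNA integrity, was 1.55 and 1.02 in wild type and 0.944 and 0.931 in bitransgenic skin. For beta-actin it was 1.66 and 1.53 in wild type and 1.70 and 1.54 in bitransgenic skin, with no split by genotype. Bacillus spike-in signals averaged 954 and 218 in wild type replicates 1 and 2, and 1071 and 289 in bitransgenic replicates 1 and 2. Replicate number thus split the arrays by spike-in signal, with both genotypes at each level, and whether it marks a labelling batch or a dose of the spike is not known. Eif2s3y, a Y-linked gene, had signals of 1922 and 1212 in wild type replicate 1 and bitransgenic replicate 2, against 22.5 and 16 in the other 2 arrays, where Xist was high at 5182 and 6195. Each genotype thus had 1 array with high Y-linked signal and 1 with high Xist.

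The first question was whether the gene of the transgene was higher in bitransgenic skin. The array reads Trp63 with 4 probe sets, here called A to D in the order of their identifiers, and they differed. The signal of B was 522 ± 447 (SD) in wild type and 12786 ± 3480 in bitransgenic skin, a 28.9-fold difference (log2 difference 4.85 ± 0.61, SE). For C the signals were 317 ± 221 and 7282 ± 3731, a 23.1-fold difference (4.53 ± 0.57). The brightest wild type probe set, A, read 5390 ± 597 and 5239 ± 89.0 (-0.037, 95% interval -0.62 to 0.55), so a difference of 2-fold in either direction lay outside its interval. Probe set D read 1199 ± 979 and 975 ± 844 (-0.33, 95% interval -2.29 to 1.63). In limma's fit of 45037 probe sets the adjusted p was 0.0613 for B, 0.0591 for C, 0.983 for A and 0.943 for D. B and C missed the threshold there, but passed it with replicate number as a block (0.00388 and 0.00124) and over the 27022 probe sets past the filter (0.0345 and 0.0343), a setting added after the data were seen. The block leaves fewer residual degrees of freedom than the main fit, so its p values rest more on the prior. By the rule of the highest mean, Trp63 entered the gene tests through A, with an adjusted p of 0.961. The mean of its probe sets past the filter gave 2.25 (adjusted p = 0.0177).

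**Figure D1:**
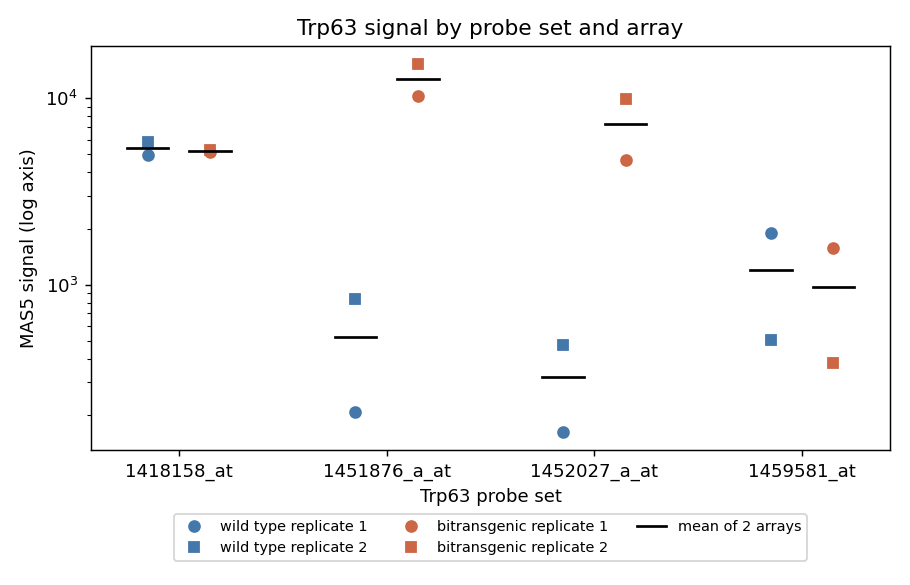
MAS5 signal (log axis) of the 4 Trp63 probe sets (A to D from left to right) on each of the 2 wild type (blue) and 2 bitransgenic (orange) arrays, with bars at the mean of each group. Bitransgenic arrays read 10325 and 15247 with B against 205.7 and 837.8 in wild type, while the groups met at A.

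The main comparison asked which genes differed between deltaNp63alpha-overexpressing and wild type skin. Of 13070 genes tested with limma, 98 were higher and 206 lower in bitransgenic skin, each by 2-fold or more. A difference of 8-fold or more was seen for 25 of the higher and 106 of the lower genes. At an unadjusted p under 0.05 there were 903 higher and 1275 lower genes. In 48.8% of genes the arrays of the groups did not overlap, against 33.3% by chance. All 304 called genes had the same direction within replicate 1 and within replicate 2, by 2-fold or more in each. All 304 were called again with replicate number as a block, which called 207 higher and 438 lower genes. Both come from the arrays that gave the calls, so neither is independent support. The counts depended on single arrays. They were 173 higher and 331 lower without wild type replicate 1, 314 and 635 without wild type replicate 2, 22 and 96 without bitransgenic replicate 1, and 30 and 124 without bitransgenic replicate 2. With no filter on dim probe sets they were 52 and 132.

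The largest rise was that of Lce3f, a late cornified envelope gene of epidermal repair, from 15.8 ± 11.5 (SD) to 3810 ± 1264 (log2 difference 6.92 ± 0.41, SE; adjusted p = 0.00346). Krt6b, a keratin of wounded and hyperproliferative epidermis, rose 47.5-fold, from 587 ± 666 to 17938 ± 919 (adjusted p = 0.0332), and missed the threshold without bitransgenic replicate 1 (0.0892) or replicate 2 (0.0685). Cdhr1, a cadherin known from photoreceptors, rose by 5.19 on the log2 scale, and Lce3c by 4.87. Stfa3, a stefin that inhibits cysteine proteases, rose 27.4-fold from 533 ± 28.6 to 15431 ± 5002 (adjusted p = 0.00346). Fgfbp3, which binds fibroblast growth factors, rose 26.6-fold from 115 ± 15.3 to 3471 ± 228. The cornified envelope precursor Sprr2f rose 24.4-fold, and Ang2, a ribonuclease of the angiogenin family, rose by 4.43 on the log2 scale. Wild type signals of Lce3f, Cdhr1, Lce3c and Ang2 lay below the filter's signal of 57.0, so the size of these rises depends on the pseudocount. For Lce3f the log2 difference was 7.98 with a pseudocount of 1 and 5.57 with 64.

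Of the 8 largest falls, 6 were of genes of hair structure. Krtap19-3 fell by 7.53 ± 0.61 on the log2 scale, from 6726 ± 3111 to 24.6 ± 30.1 (adjusted p = 0.00624). Krtap11-1, Krtap16-3 and Krtap14, which also code for proteins of the hair shaft matrix, fell, with log2 differences of -7.27, -6.83 and -6.65. The trichohyalin-like gene Tchhl1 fell from 8381 ± 435 to 44.5 ± 26.1 (log2 difference -7.19 ± 0.36, adjusted p = 0.00331), and the hair keratin Krt86 fell from 10915 ± 4139 to 125 ± 170 (-7.15 ± 1.07). Outside hair structure, the thyroid hormone-binding protein Crym fell from 15064 ± 7710 to 204 ± 245 (-6.70 ± 0.94). Hamp2, a hepcidin gene, fell from 3648 ± 2241 to 10.8 ± 2.33. Both bitransgenic signals of Krtap19-3 and Hamp2 lay below 57.0, as did those of Tchhl1, Krtap11-1, Krt86, Krtap16-3 and Crym in bitransgenic replicate 1, so the size of these falls depends on the pseudocount too. For Krt86 the log2 difference was -8.11 with a pseudocount of 1 and -6.18 with 64. With a pseudocount of 1 Krtap11-1 (adjusted p = 0.0636) and Krt86 (0.0594) missed the threshold. Probe sets of Lce3c, Hamp2, Krtap11-1 and Krtap16-3 carry the suffix _x_at or _s_at and can also read close relatives of the gene.

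**Figure D2:**
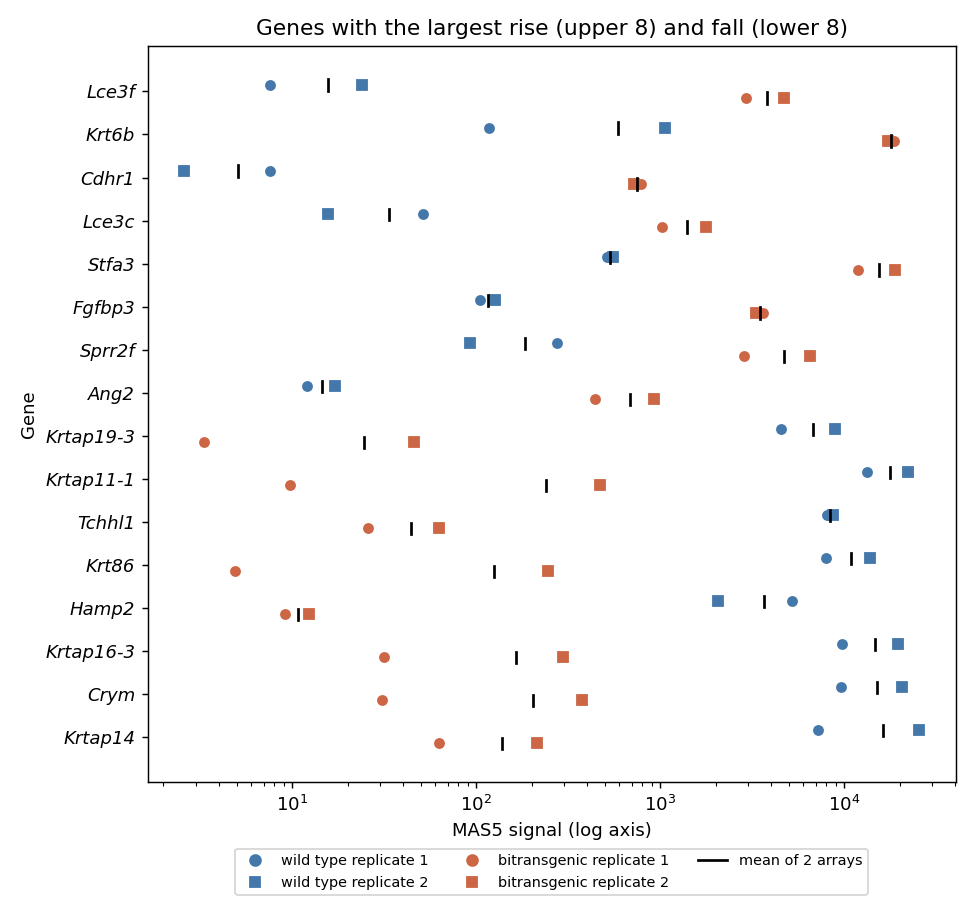
MAS5 signal (log axis) of the 8 genes with the largest rise and the 8 with the largest fall, 1 point per array, blue for wild type and orange for bitransgenic, with circles for replicate 1 and squares for replicate 2. For every gene both bitransgenic arrays lie on one side of both wild type arrays, as the rule for naming them required.

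Camera called 3 lists of hair structure lower in bitransgenic skin, with an adjusted p = 0.423 for each with an estimated correlation. Of 36 keratin-associated proteins, which cross-link hair keratins, 34 fell and 2 did not pass, with a median 46.3-fold lower (log2 -5.53). Of 12 hair shaft keratins, 10 fell and the median was 25.9-fold lower, with Krt81 falling from 11509 ± 3757 to 472 ± 288 (adjusted p = 0.00927). Among 15 genes of the inner root sheath and companion layer, the layers that mould the growing shaft, 4 fell and the median was 24.2-fold lower. Krt72 fell 81.7-fold, and the arginine deiminases Padi1 and Padi3 fell 21.3-fold and 24.3-fold. Adjusted over the list alone, 36 keratin-associated proteins, 12 shaft keratins and 14 inner sheath genes fell. Camera gave adjusted p values of 4.11e-46, 3.85e-15 and 4.2e-11 for these 3 lists at the preset correlation (adjusted p = 0.423 for each with an estimated correlation). Their medians were -6.18, -5.02 and -5.24 within replicate 1, and -4.97, -4.63 and -2.91 within replicate 2. The inner sheath median was -2.55 without bitransgenic replicate 1. Its number of called falls was 6 without wild type replicate 1 or 2, 7 without bitransgenic replicate 1, 10 without bitransgenic replicate 2 and 12 with replicate number as a block.

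Of 16 hair matrix and precortex regulators, the growth factor genes Bmp4 and Fgf5 fell, with log2 differences of -2.70 ± 0.36 and -3.91 ± 0.69, and 9 fell when adjusted over the list alone. Both bitransgenic signals of Fgf5 lay below 57.0, and its log2 difference was -4.78 with a pseudocount of 1 and -2.81 with 64. The value of Msx2 was -3.55 (adjusted p = 0.0682, or 0.00221 with the block). Lef1 and Shh, chosen after their values were seen, had values of -2.86 and -2.69 (adjusted p = 0.13 and 0.137). Wild type replicates 1 and 2 differed in both, with signals of 185 and 1115 for Lef1 and 249 and 1384 for Shh. The list median was -1.52 (camera adjusted p = 3.03e-05; adjusted p = 0.439 with an estimated correlation), -1.13 within replicate 1, -1.89 within replicate 2 and -0.92 without wild type replicate 2. The number of its genes that fell was 9 and 2 without wild type replicate 1 or 2, 0 and 2 without bitransgenic replicate 1 or 2, and 6 with the block. Of 18 bulge stem cell genes, Krt15 fell from 20204 ± 6050 to 5063 ± 1744 (adjusted p = 0.0424), and 7 fell when adjusted over the list alone. Lgr5 read 1365 ± 15.3 and 499 ± 96.7 (adjusted p = 0.0574, or 0.0378 with the block). The bulge median was -0.69 (adjusted p = 0.000979; adjusted p = 0.466 with an estimated correlation), -1.03 within replicate 1 and -0.091 within replicate 2, and the call was lost without wild type replicate 1 (-0.28, adjusted p = 0.0824). Without wild type replicate 2, 6 bulge genes fell, without bitransgenic replicate 1 none did, and with the block 3 did. None of 12 dermal papilla genes passed, adjusted over the list alone included, with a median of -0.51 (adjusted p = 0.0127; adjusted p = 0.423 with an estimated correlation), -0.48 within replicate 1 and -0.51 within replicate 2, and 1 fell with the block. Without wild type replicate 1 its adjusted p was 0.124, and without bitransgenic replicate 2 it was 0.0778. Bmp4 missed the threshold without bitransgenic replicate 1 (-2.32, adjusted p = 0.0829), as did Fgf5 (-3.41, 0.162) and Krt15 (-1.65, 0.172). Fgf5 also missed it without bitransgenic replicate 2 (-4.41, 0.0616), and Krt15 without wild type replicate 1 (-1.69, 0.0515).

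Of 21 stress and hyperproliferation keratinocyte genes, 7 rose, and 14 rose when adjusted over the list alone. These included Stfa3 and Sprr2d (11.0-fold, from 162 ± 19.9 to 2012 ± 776, adjusted p = 0.00978) and Lcn2, an iron-binding antimicrobial protein (13.1-fold, from 353 ± 166 to 4758 ± 1928, adjusted p = 0.0143). The list median was 1.69, or 3.23-fold (camera adjusted p = 3.75e-14; adjusted p = 0.423 with an estimated correlation, where the unadjusted p was 0.0416). It was 2.21 within replicate 1 and 1.66 within replicate 2. The number of its genes that rose was 10 and 13 without wild type replicate 1 or 2, and 4 and 5 without bitransgenic replicate 1 or 2. Krt6a, Krt16 and Krt17, abundant members of the list chosen after their values were seen, had values of 0.44, 1.30 and 0.69 and did not pass. Of 33 cornified envelope and granular layer genes, 8 rose and 1, Lce1m, fell by 3.89. The 8 were Lce3f, Lce3c, Lce3a, Lce1f, Lce1i, Lce1h, the filaggrin gene Flg and Casp14, a protease that processes filaggrin. Adjusted over the list alone, 9 rose and 4 fell. Lce1i rose 4.05-fold, from 1618 ± 71.1 to 6597 ± 391 (adjusted p = 0.0127), but missed the threshold without bitransgenic replicate 1 (1.96, adjusted p = 0.0793) or replicate 2 (2.08, 0.0538). The median of the list was 0.15 (adjusted p = 0.0396; adjusted p = 0.423 with an estimated correlation), -0.014 within replicate 1 and 0.48 within replicate 2. Its adjusted p was 0.0731 with the block, 0.124 without wild type replicate 2 (median 0.035) and 0.0783 without bitransgenic replicate 1. Only 2 and 3 of its genes rose without bitransgenic replicate 1 or 2, 5 rose without probe sets of suffix _x_at or _s_at, and 3 fell with the block.

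Among reported p63 target genes, 0 of 32 tested passed limma's threshold over all genes, 1 fell when adjusted over the list alone, and 2 fell with the block. The list was not split by whether p63 raises or lowers a gene. Rises and falls would thus cancel in its median and in camera, which cannot show whether the targets responded. Of these 32, 20 also belong to another of the lists. The list had 15 positive and 17 negative values, with a median of -0.023 (adjusted p = 0.761; adjusted p = 0.989 with an estimated correlation) that turned to 0.0089 under quantile normalization and 0.069 with equal array medians. Krt5, Krt14 and Fras1 were chosen after their values were seen. Krt5 and Krt14, the keratins of the basal layer, had values of -0.023 ± 0.34 and 0.23 ± 0.29. Fras1, which codes for a basement membrane protein, read 246 ± 51.6 and 51.3 ± 4.67 (adjusted p = 0.0531, or 0.0431 with the block). None of 17 basal keratinocyte genes and none of 14 desmosome and adhesion genes passed, and none did when adjusted over the list alone. Their medians were 0.078 and -0.091 (adjusted p = 0.997 for each), the second of which turned to 0.0011 with equal array medians. Of 14 spinous genes none passed, while 1 rose and 1 fell when adjusted over the list alone and 2 rose and 1 fell with the block, with a median of 0.33 (adjusted p = 0.212) that passed without bitransgenic replicate 1 (0.42, adjusted p = 0.0193). Krt1 and Krt10, chosen after their values were seen, had values of 1.58 ± 0.40 (adjusted p = 0.111) and -0.27 ± 0.27.

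All 31 cell division genes had higher mean values in bitransgenic skin, although none passed alone, adjusted over the list alone included. Mcm4, a replication helicase subunit, read 764 ± 101 and 1556 ± 69.7 (adjusted p = 0.109), and Cdca8, of the chromosomal passenger complex, read 434 ± 223 and 1256 ± 132 (adjusted p = 0.109, or 0.042 with the block, where 2 genes of the list rose). The median was 0.99, or 1.99-fold (camera adjusted p = 1.98e-10; adjusted p = 0.463 with an estimated correlation). It was 1.54 within replicate 1 and 0.53 within replicate 2, and 0.35 without wild type replicate 1 against 1.75 without wild type replicate 2. The cell division median of wild type replicate 2 minus wild type replicate 1 was 1.39, and that of the bitransgenic arrays 0.36. The 2 wild type arrays thus differed by more than the genotypes did. The estimated correlation within the list was 0.787, so its 31 genes are not independent. Without wild type replicate 2, 23 of the 31 rose, against 0, 0 and 1 without wild type replicate 1, bitransgenic replicate 1 or bitransgenic replicate 2.

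Of 13 Wnt pathway targets, Bmp4 fell, and 7 fell when adjusted over the list alone, with a median of -1.43 (adjusted p = 1.78e-06; adjusted p = 0.423 with an estimated correlation). Of these 13, 5 also belong to another of the lists, as do 3 of the 18 BMP genes below. Bmp4 itself is in the hair matrix, Wnt target and BMP lists, so their falls are not independent. The Wnt antagonist Nkd2 had a value of -1.84 (adjusted p = 0.0568, or 0.0231 with the block). Of 18 BMP pathway genes, Bmp4 and Bambi, a pseudoreceptor for the family, fell. Bambi fell 13.3-fold, from 3958 ± 2486 to 262 ± 101 (adjusted p = 0.0207), and 7 genes fell when adjusted over the list alone. The BMP median was -0.50 (adjusted p = 0.000134; adjusted p = 0.423 with an estimated correlation). The number of falls without wild type replicate 1 or 2 was 5 and 3 for Wnt targets and 2 and 3 for BMP genes, and without bitransgenic replicate 1 or 2 it was 0 and 2 for each list. With the block 4 fell in each. Medians within replicates 1 and 2 were -1.02 and -1.23 for Wnt targets, and -0.56 and -0.42 for BMP genes. Camera passed neither the 20 Wnt ligands, receptors and inhibitors (median -0.16, adjusted p = 0.225), nor the 10 hedgehog genes (-0.21, 0.144), nor the 13 Notch genes (-0.12, 0.225). Wnt5a fell 7.54-fold (adjusted p = 0.0298) and the hedgehog receptor Ptch1 fell 2.97-fold (0.0434), each also the only fall of its list when adjusted over the list alone, and no Notch gene passed either way, although 1 fell with the block. Without bitransgenic replicate 1, the adjusted p was 0.123 for Wnt5a (-2.72), 0.24 for Ptch1 (-1.44) and 0.0653 for Bambi (-3.35). Without bitransgenic replicate 2 it was 0.0697 for Wnt5a (-3.11) and 0.136 for Ptch1 (-1.70). The Wnt ligand list passed with no filter (-0.26, adjusted p = 0.0461) and without bitransgenic replicate 2 (-0.36, 0.0352), and the hedgehog list passed with no filter (-0.42, 0.0461).

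Of 19 cytokine and chemokine genes, Ccl20, Ccl2, Tslp and Cxcl9 rose, and 8 rose and 1 fell when adjusted over the list alone. Ccl20, which attracts dendritic cells and interleukin-17-producing T cells, rose from 44.5 ± 34.9 to 1008 ± 11.1 (log2 4.21 ± 0.47, adjusted p = 0.0127). Ccl2, which attracts monocytes, rose 6.27-fold, from 71.3 ± 0.424 to 540 ± 138, and the keratinocyte cytokine Tslp rose from 52.9 ± 0.636 to 412 ± 139 (adjusted p = 0.0274). The median was 1.09 (adjusted p = 1.85e-06; adjusted p = 0.423 with an estimated correlation), and 0.71 without wild type replicate 2. The number of its genes that rose was 7 and 4 without wild type replicate 1 or 2, and 1 without either bitransgenic array. Of 12 interferon-stimulated genes, Oas1a rose 4.57-fold (adjusted p = 0.0211), and 7 rose when adjusted over the list alone, with a median of 1.03 (adjusted p = 8.12e-05; adjusted p = 0.423 with an estimated correlation). Without wild type replicate 1 or 2, 3 and 2 interferon-stimulated genes rose, without either bitransgenic array none did, and with the block 4 did. Medians within replicates 1 and 2 were 0.94 and 1.52 for cytokines, and 0.87 and 1.01 for interferon-stimulated genes. Without bitransgenic replicate 1 the adjusted p was 0.129 for Ccl2 (2.39), 0.0697 for Tslp (2.94) and 0.171 for Oas1a (1.996). Without bitransgenic replicate 2 it was 0.0578 for Ccl2 (2.90), 0.125 for Tslp (2.26) and 0.0806 for Oas1a (2.39).

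None of 18 macrophage genes passed over all genes, but 10 rose when adjusted over the list alone and all 18 had positive values. Lyz2 read 4059 ± 846 and 10637 ± 3481 (adjusted p = 0.0905). The macrophage median was 1.04 (camera adjusted p = 2.87e-09; adjusted p = 0.423 with an estimated correlation), 0.52 within replicate 1 and 1.52 within replicate 2, with 3 macrophage genes rising without wild type replicate 1 and 1 with the block. Of 11 genes of antigen-presenting and Langerhans cells none passed, and H2-Eb1, the lowest at -2.36, fell when adjusted over the list alone and with the block (adjusted p = 0.0413). Their median was 0.88 (adjusted p = 0.0401; adjusted p = 0.629 with an estimated correlation), 0.087 within replicate 1 and 1.77 within replicate 2. Its adjusted p was 0.0541 with the block, 0.354 without wild type replicate 2 (0.47) and 0.454 without bitransgenic replicate 2 (0.34). Of 10 T cell genes, Cd7 fell from 267 ± 37.7 to 16.2 ± 1.27 (log2 -3.13 ± 0.36, adjusted p = 0.0144), also the only fall when adjusted over the list alone, and its adjusted p was 0.0604 without bitransgenic replicate 1 (-3.09). Both bitransgenic signals of Cd7 lay below 57.0, so the size of its fall depends on the pseudocount (-3.96 with 1 and -2.04 with 64). The T cell list (median 0.039, adjusted p = 0.882) and the 9 mast cell genes (0.049, 0.437, none passing either way) did not pass.

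Of 18 cholesterol synthesis genes, Idi1 rose 3.21-fold, from 2168 ± 25.2 to 7142 ± 2019 (adjusted p = 0.0358), and Cyp51 rose 3.03-fold, from 1680 ± 17.3 to 5202 ± 1292 (adjusted p = 0.0371). Adjusted over the list alone 8 rose, with a median of 0.79 (camera adjusted p = 1.66e-07; adjusted p = 0.423 with an estimated correlation), 1.05 within replicate 1 and 0.59 within replicate 2. Idi1 and Cyp51 missed the threshold without bitransgenic replicate 1 (1.39, adjusted p = 0.200, and 1.34, 0.226) and without replicate 2 (1.98, 0.0578, and 1.85, 0.0754). Leaving out wild type replicate 2 gave 4 rises in the cholesterol list, while no filter, eBayes without the trend and the mean of probe sets each gave 0. None of 15 sebaceous gland genes passed over all genes and 2 rose when adjusted over the list alone. Krt79 read 11927 ± 681 and 28816 ± 7928 (adjusted p = 0.0837, or 0.0292 with the block, where 2 genes of the list rose and 1 fell). The sebaceous median was 0.40 (adjusted p = 0.0492; adjusted p = 0.621 with an estimated correlation), 0.66 within replicate 1 and 0.17 within replicate 2. That call was lost without wild type replicate 1 (adjusted p = 0.0969), wild type replicate 2 (0.13) or bitransgenic replicate 1 (0.070, adjusted p = 0.91). All 15 fat cell genes had negative values and none passed, while 7 fell when adjusted over the list alone. Adipoq read 11627 ± 5846 and 3845 ± 393 (adjusted p = 0.11). The fat cell median was -1.005 (camera adjusted p = 1.71e-07; adjusted p = 0.423 with an estimated correlation), -1.55 within replicate 1 and -0.61 within replicate 2, with 6 fat cell genes falling without wild type replicate 2 and 2 with the block.

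All 21 skeletal muscle genes, which mark the sheet of muscle under mouse skin, had negative values, 9 fell, and 20 fell when adjusted over the list alone. Myh4, a fast myosin, fell 39.1-fold, from 19960 ± 13941 to 586 ± 574 (adjusted p = 0.0323), and Myl1 fell 6.67-fold, from 23404 ± 6517 to 3515 ± 1098 (adjusted p = 0.0152). The muscle median was -2.89 (camera adjusted p = 1.14e-17; adjusted p = 0.423 with an estimated correlation), -3.87 within replicate 1 and -1.97 within replicate 2. The muscle median of wild type replicate 2 minus wild type replicate 1 was -1.64, and that of the bitransgenic arrays 0.26. Without bitransgenic replicate 1 or 2, 1 and 4 muscle genes passed, and without wild type replicate 1 or 2, 13 and 21. The number of muscle falls was 18 with the block, 2 with no filter, 2 with eBayes without the trend and 5 with the mean of probe sets. Myl1 had an adjusted p of 0.0505 without bitransgenic replicate 1 (-2.41). All 19 dermal fibroblast and matrix genes had negative values and none passed, with 9 falling when adjusted over the list alone. Col1a1 read 22940 ± 1658 and 8521 ± 2143 (adjusted p = 0.0531, or 0.019 with the block, where 5 genes of the list fell). Their median was -0.78 (adjusted p = 5.04e-08; adjusted p = 0.439 with an estimated correlation), -1.20 within replicate 1 and -0.46 within replicate 2. Without wild type replicate 2, 6 of them fell, and without bitransgenic replicate 2, 1. Of 11 Schwann cell and nerve genes, the myelin gene Mal fell 6.97-fold (adjusted p = 0.0201), and 6 fell when adjusted over the list alone. That median was -1.18 (adjusted p = 3.03e-05; adjusted p = 0.439 with an estimated correlation), -1.76 within replicate 1 and -0.54 within replicate 2. The call of Mal was lost without bitransgenic replicate 1 (-2.40, adjusted p = 0.0808), and the Schwann cell median was -0.76 without wild type replicate 1. Schwann cell genes that fell numbered 4 without wild type replicate 2 and 3 with the block.

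The median of the melanocyte genes rested on 1 array. Of 14, Mitf, the lineage's transcription factor, fell 4.32-fold (adjusted p = 0.0201) and Rab38, which carries pigment enzymes, rose 3.36-fold (0.042), also the only 2 calls when adjusted over the list alone. Both were lost without bitransgenic replicate 1 (-2.20, adjusted p = 0.0829, and 1.58, 0.221) and without replicate 2 (-2.02, 0.0858, and 1.92, 0.106). The median was -1.20 (adjusted p = 0.00493; adjusted p = 0.466 with an estimated correlation), but -0.055 within replicate 1 and -2.002 within replicate 2, and it turned to 0.088 without wild type replicate 2 (adjusted p = 0.96). Melanocyte genes that fell numbered 8 without wild type replicate 1. Of 5 red blood cell genes, the anion exchanger Slc4a1 fell 4.86-fold (adjusted p = 0.0266), and 1 rose and 2 fell when adjusted over the list alone. It missed the threshold without bitransgenic replicate 1 (-2.17, 0.138) or replicate 2 (-2.39, 0.0893). The red cell list did not pass (median 0.070, adjusted p = 0.437), and neither did the 15 endothelial genes (-0.020, 0.882, none passing either way), whose median turned to 0.062 under quantile normalization and 0.071 with equal array medians.

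Camera at its preset correlation passed 9 of 33 lists upward and 13 downward. With replicate number as a block it passed 20, all among these 22, and with an estimated correlation it passed 0, the smallest adjusted p being 0.423. For basal keratinocytes, red blood cells and T cells, none of which passed, camera's direction was down while the list median was above 0. The median log2 difference of all 13070 genes was 0.0053. Of 92 called genes with more than 1 probe set past the filter, 4 had another probe set of the opposite sign, and 0 of those passed by itself.

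**Figure D3:**
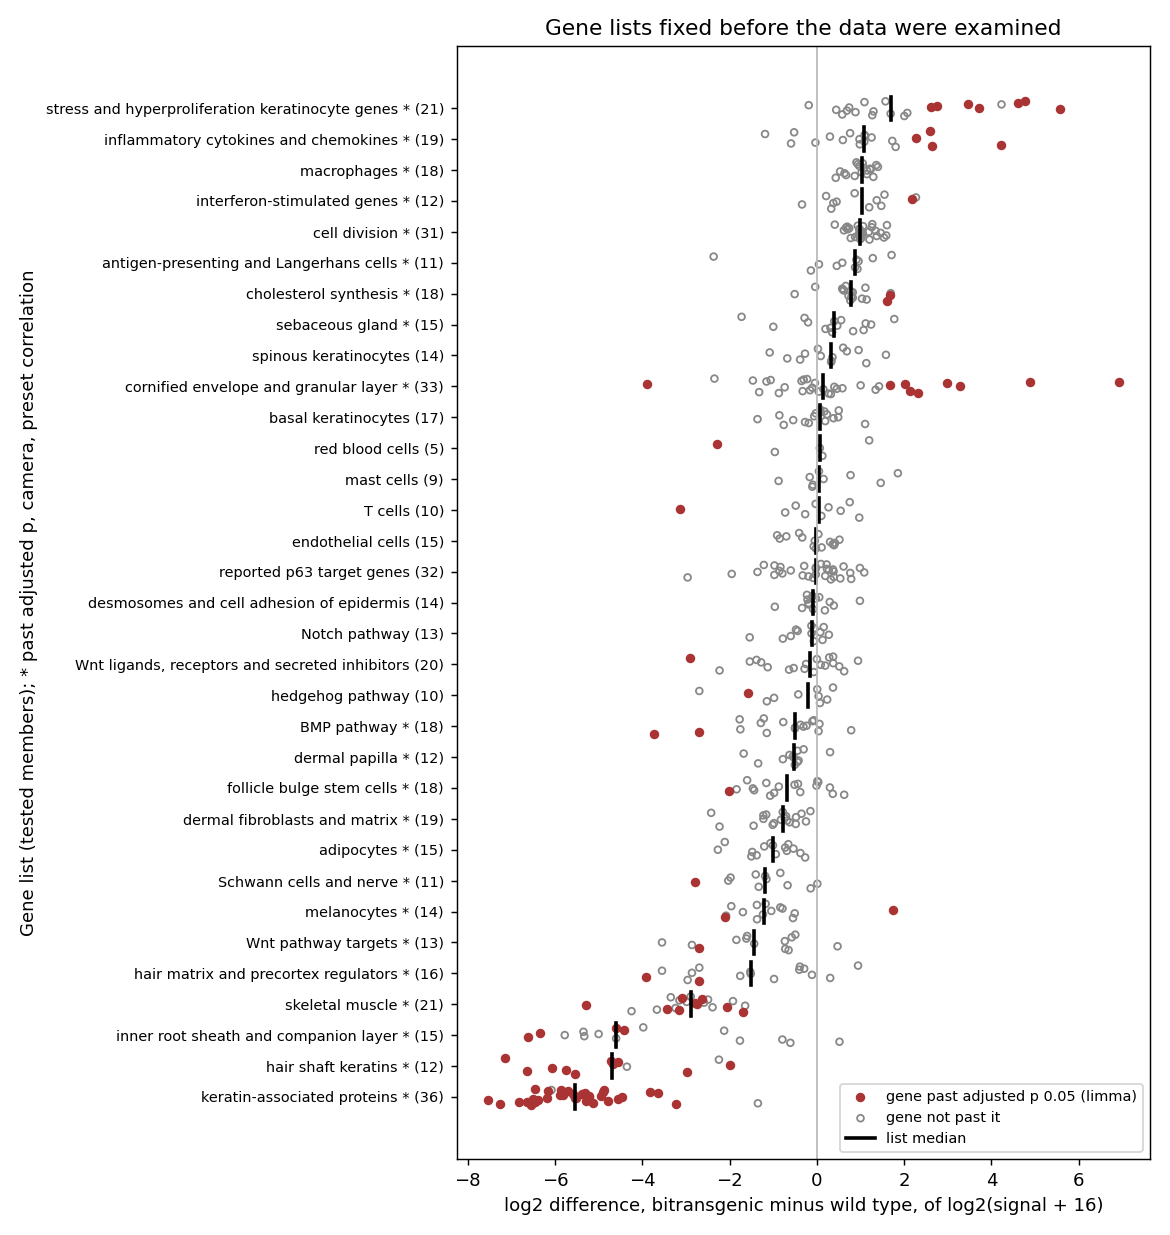
Log2 difference (bitransgenic minus wild type) of each tested member of the 33 gene lists, 1 point per gene, red when past the adjusted p threshold, with a bar at the list median. Medians run from -5.53 for keratin-associated proteins to 1.69 for stress and hyperproliferation genes.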

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

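In this part the count over other splits of the arrays was planned, and all other tests of explanations were chosen after the result was seen. Of the 3 ways to part the 4 arrays into 2 and 2, 1 called as many genes as genotype did. That was the genotype split itself, with 304 genes, while the highest other split called 0. The others followed the level of spike-in signal, or parted arrays with high Xist from arrays with high Y-linked signal. They leave the genotype difference in the spread within their groups, which makes calls unlikely. The Xist split called 0 although Eif2s3y read 1922 and 1212 on 1 side and 22.5 and 16 on the other. A count of 0 is thus no evidence against effects of sex or spike-in level. With 3 splits the share cannot fall under 0.05.

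Probe sets without a single gene symbol lay outside the gene comparisons, and some of them were past limma's threshold. Among 3839 of them tested, 6 were higher in bitransgenic skin and 17 lower. The log2 difference was 7.25 for the highest of them, with signals of 34.1 and 12.4 in wild type and 19019 and 1711 in bitransgenic skin, and 4.48 for the next, with 403.9 and 1020 against 9553 and 22681. No explanation was tested for either.

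The fall of keratin-associated proteins could come from the scaling of the arrays or from less deep tissue in the bitransgenic pieces. After quantile normalization their median was -5.51 and their upper quartile -4.95. That step moved the median of all genes only from 0.0053 to 0.041, so it could hardly have changed so large a fall. A scaling difference would shift all genes alike, and their median near 0 argues against scaling as the cause. Growing follicles reach into the fat, yet the lower quartile of the fat cell list, -1.43, lay far above the upper quartile of the keratin-associated proteins, -4.93. Skeletal muscle, the deepest tissue in the piece, was lower in all 21 members, which goes with less deep tissue, but its median of -2.89 and lower quartile of -3.24 also lay above -4.93. Less deep tissue is thus argued against as the whole cause only if a shallower cut takes fat and muscle at least as far as follicle bases. That was not measured, and less deep tissue could be part of the fall. An effect of the transgene on follicles, directly or through an earlier end of the hair growth phase, remains a hypothesis that these arrays at 1 age do not test. The median of wild type replicate 2 minus wild type replicate 1 was 1.33 for hair matrix regulators and 0.61 for keratin-associated proteins. The labels do not give the stage of hair growth, so a difference in stage between animals cannot be told apart from such an effect.

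The fall of skeletal muscle genes could reflect how much of the muscle sheet was taken with each piece of skin, a labelling batch, or a difference in the animals. The median differed by -1.64 between the 2 wild type arrays and by 0.26 between the bitransgenic arrays, against -2.89 between genotypes, so the amount of muscle taken cannot be told apart from genotype with 2 arrays per group. Each replicate number, which the spike-in signals told apart, held both genotypes, so a batch effect alike in both would cancel in the comparison. The median was -1.97 in replicate 2 alone and -3.87 in replicate 1. This argues against a batch marked by replicate number as the cause. Whether replicate number marks a labelling batch is not known, and a batch of another kind was not tested. A biological difference in muscle stays open as well and was not tested.

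The Trp63 probe sets disagreed, with B and C far higher in bitransgenic skin and A level. The highest signal of A was 15.5% of the brightest signal on its array, so A lay well under the top of the array's range. Probe sets can level off at different signals and single probes were not examined, so saturation of A itself is not excluded. A candidate explanation is a transgene transcript that lacks the part of the mRNA read by A. The difference of B exceeded that of A by 4.89 on the log2 scale, but the positions of the probes were not used here, which keeps this open. A level endogenous transcript beside a high transgene transcript would be the corresponding biological reading, and it stays a hypothesis.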

How the results depend on the processing

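The filter at the 40th percentile for single Trp63 probe sets was added after the data were seen, and the other alternatives were planned. All 304 called genes kept their direction in every alternative that tested them, with 299 tested with a pseudocount of 1, 291 without _x_at and _s_at probe sets and 263 with the filter at the 60th percentile. The counts under quantile normalization, equal medians, both pseudocounts, both other eBayes settings, the mean of probe sets and the 60th percentile stayed within 1.5 times of the 98 higher and 206 lower genes, and 182 to 304 of the calls were shared, in these and with no filter. The same 3 hair lists, stress genes, cell division, Wnt targets, BMP genes, cytokines, interferon-stimulated genes, cholesterol synthesis, fat cells, muscle, fibroblasts, macrophages and Schwann cells passed camera at the preset correlation in every alternative, as did hair matrix regulators. Depth is set here by signal over background, so genes under a signal of 57.0 in a group have no firm fold. Leaving out an array leaves a lone array in its group, which is then assumed to vary like the other group. Replicate numbers share a level of spike-in signal, but whether they mark a labelling batch or pair animals is not stated: with 2 numbers, the differences of replicate 1 from replicate 2 had r = 0.211 between genotypes over 13070 genes, which are not independent. The replicate block gave 207 higher and 438 lower genes, ended the calls of the cornified list (0.15, adjusted p = 0.0731) and the antigen-presenting list (0.88, 0.0541) with their medians unchanged, and passed Trp63 probe sets B (4.85) and C (4.53). It ended no other list call and no call of a named gene.

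Where a value changed side or sign, the cause was not tested unless stated. No filter, with more genes to adjust over, gave 52 higher and 132 lower genes, and probe sets tested each by itself gave 56 higher. The estimated correlation left 0 lists. The cornified median was 0.10 under quantile normalization, 0.24 with equal medians, 0.10 with no filter, and 0.045 with the 60th percentile filter and without _x_at and _s_at probe sets, each not past the threshold (adjusted p 0.0512 to 0.269). The antigen-presenting median, likewise, was 0.85 under quantile normalization, 0.97 with equal medians, 0.89 at the 60th percentile, 0.58 with the mean of probe sets and 0.73 without _x_at and _s_at probe sets (0.0514 to 0.257). The sebaceous list missed the threshold with equal medians (0.49, adjusted p = 0.0705), without the trend (0.40, 0.0789) and without _x_at and _s_at probe sets (0.40, 0.0519). Passing with no filter were Wnt ligands (-0.26) and hedgehog genes (-0.42). The p63 target median was 0.0089 under quantile normalization, 0.069 with equal medians and 0.017 with the mean of probe sets. The endothelial median was 0.062, 0.071 and, without _x_at and _s_at probe sets, 0.011. Desmosome genes turned to 0.0011 with equal medians, basal keratinocytes to -0.023 with the mean of probe sets, and red blood cells to -0.42 at the 60th percentile and -0.13 with the mean of probe sets. At the 60th percentile hedgehog genes read 0.010, T cells -0.027 and mast cells -0.090, and without _x_at and _s_at probe sets the last 2 read -0.027 and -0.020. Of named genes, H2-Aa changed sign, to -0.038 with the mean of probe sets, and Trp63 as a gene changed sign too. It read 0.055 with equal medians and 2.25 with the mean of probe sets, which takes in B and C. By probe set, A read 0.042 with equal medians, B 4.93 and C 4.61, the last 2 then past the threshold, as was C with a pseudocount of 1 (4.61) and both with the filter at the 40th percentile (4.85 and 4.53), which leaves fewer probe sets to adjust over.

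Leaving out 1 array at a time gave 22 to 314 higher genes, 96 to 635 lower genes and 18 to 21 lists. Ranges of medians were -0.83 to -0.28 for bulge genes, -0.70 to -0.36 for dermal papilla, 0.035 to 0.31 for cornified, 0.070 to 0.63 for sebaceous, 0.34 to 1.41 for antigen-presenting and -1.99 to 0.088 for melanocyte genes. For lists not called they were -0.25 to 0.34 for basal, 0.15 to 0.45 for spinous, -0.24 to 0.24 for desmosome, -0.25 to 0.23 for p63 target, -0.36 to 0.069 for Wnt ligand, -0.48 to -0.051 for hedgehog, -0.25 to -0.016 for Notch, -0.28 to 0.31 for T cell, -0.16 to 0.35 for mast cell, -0.21 to 0.29 for endothelial and -0.32 to 0.11 for red cell genes. Trp63 as a gene and its probe set A read -0.15 to 0.076, B 3.88 to 5.82, C 3.80 to 5.26 and D -1.34 to 0.67. Of 48 named genes past the threshold, 47 and 48 stayed past it without wild type replicate 1 or 2, and 28 and 34 without bitransgenic replicate 1 or 2. All 48 stayed past it with the replicate block and with robust eBayes. Calls were lost for 10 with no filter (Krt6b, Krtap11-1, Fgf5, Krt15, Ptch1, Tslp, Idi1, Cyp51, Myh4 and Rab38), and for 9 without the trend (these but for Tslp). With the mean of probe sets 7 were lost (Krtap11-1, Fgf5, Krt15, Wnt5a, Ptch1, Idi1 and Cyp51), with a pseudocount of 1 Krtap11-1, Krt86 and Fgf5, with one of 64 and under quantile normalization Fgf5, and with equal medians Ptch1. Within lists, cytokine genes that rose numbered 2 with no filter against 4, and hair matrix genes that fell numbered 1 against 2 under quantile normalization, both pseudocounts, no filter, the 60th percentile, no trend and the mean of probe sets.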

Other observations

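All genes, families and tests in this part were chosen after their values were seen. The single genes named here were not tested as groups. Gstm5, a glutathione transferase, rose from 4481 ± 95.9 to 20842 ± 989 (SD; log2 difference 2.21 ± 0.22, SE; adjusted p = 0.00935 by limma). The carbonyl reductase Cbr3 rose by 1.96, the aldehyde dehydrogenase Aldh3a1 by 2.34 and the glutathione transferase Gsto1 by 1.56, with adjusted p values of 0.0175, 0.0343 and 0.0442. Of 19 genes with stem Aldh, 1 rose, and the median was 0.011 (camera adjusted p = 0.942). Duox1, an oxidase that makes hydrogen peroxide, rose from 101 ± 10.7 to 1402 ± 603, and its maturation factor Duoxa1 from 798 ± 147 to 3254 ± 202 (adjusted p = 0.0126 and 0.0174). The glucose transporter Slc2a1 rose from 865 ± 190 to 5478 ± 416 (adjusted p = 0.00907), and Epgn, a ligand of the epidermal growth factor receptor, from 414 ± 169 to 6039 ± 1106 (adjusted p = 0.00781). Pitx1, a homeobox gene of the hindlimb, read 25.5 ± 25.5 in wild type and 729 ± 52.7 in bitransgenic dorsal skin (4.32 ± 0.50, adjusted p = 0.0143). Wild type signals of Pitx1 lay below 57.0, so the size of its rise depends on the pseudocount. Each of these genes was higher in both bitransgenic arrays than in both wild type arrays. They were picked among called genes, and groups did not overlap in 48.8% of all genes, so this is no added support.

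The epithelial calcium channel Trpv6 fell from 1007 ± 180 to 90.7 ± 33.9, and the magnesium channel Trpm6 from 1135 ± 88.4 to 107 ± 18.2, with adjusted p values of 0.0127 and 0.00781. Of 243 genes with stem Slc, which code for transporters, 3 rose and 5 fell, with a median of -0.033 (camera adjusted p = 0.961). The metallothionein Mt4 fell from 11490 ± 7455 to 432 ± 294, and arginase 1, Arg1, from 2350 ± 1115 to 226 ± 11.0 (adjusted p = 0.0194 and 0.015). The macrophage elastase Mmp12 rose from 58.1 ± 24.5 to 835 ± 395 (adjusted p = 0.0199), while the keratinocyte alarmin S100a8 read 3884 ± 3237 and 5274 ± 528 and did not pass (adjusted p = 0.6).

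Granzyme B (Gzmb) rose from 9.85 ± 3.89 to 390 ± 165 (adjusted p = 0.0127), and Ctla4, Icos, Tnfrsf9 and Tnfrsf18 rose by 2.39, 2.25, 1.85 and 1.70 on the log2 scale. These 5 genes were picked one by one and not tested as a group. Wild type signals of Gzmb and Ctla4 lay below 57.0, so the size of their rises depends on the pseudocount. Of 14 genes with stem Tnfrsf, 2 rose, and the family did not pass (camera adjusted p = 0.0774). The fixed T cell list did not rise with them, as its median was 0.0388 and its upper quartile 0.477, both under the lowest of these rises. Its median was -0.59 within replicate 1 and 0.51 within replicate 2. Because the 5 genes were picked after their rise was seen, this comparison cannot tell whether T cells increased. No other explanation was tested. Cd3e read 215 ± 97.1 and 177 ± 86.3.

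Gene families defined by their symbol stem were screened with camera, 225 families in all. Of 10 kallikreins, proteases that act in shedding of the stratum corneum among other places, Klk8, Klk13 and Klk9 rose by 2.88, 2.61 and 2.20, and the family median was 0.75. Of 13 claudins, tight junction proteins, 3 fell, among them Cldn3 (-3.52) and Cldn23 (-2.73), and the median was -0.66. A family-wide rise of kallikreins had an adjusted p = 0.00075 at the preset correlation and an adjusted p = 0.989 with an estimated correlation. For a family-wide fall of claudins these were 0.0109 and 0.989. Whether these families moved as a whole, or through a few members, thus cannot be told apart with 2 arrays per group. The 47 mitochondrial ribosomal proteins with stem Mrpl had a median of 0.35, with 0 called genes (adjusted p = 0.000153; adjusted p = 0.989 with an estimated correlation), 0.55 within replicate 1 and 0.20 within replicate 2.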
